A study of Mus musculus with 6 samples.

How the data were processed

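Gene expression was measured by RNA sequencing in cultured mouse small-intestinal organoids, which are epithelial mini-guts with crypt-like buds and differentiated villus-like regions. Per the labels, single cells were grown for 96 h, until crypt and villus structures had formed, and were then exposed for 24 h to NIBR-LTSi at 5 uM or to a matching amount of its solvent DMSO. NIBR-LTSi is known as an inhibitor of LATS1 and LATS2, the kinases at the end of the Hippo pathway that phosphorylate the transcriptional co-activators YAP and TAZ. Each group has 3 libraries, named here by group and the replicate number in the labels, and the only comparison is NIBR-LTSi against DMSO.

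Per the labels' protocols, the organoids were brought to a single-cell suspension before RNA was purified on columns, and 200 ng of total RNA per sample entered an Illumina stranded library kit that selects messenger RNA. The authors deposited 1 table of read counts per gene for all 6 libraries, with an Entrez identifier, a symbol and a gene width in each row. Per the submitters' processing notes, the genome build was mm10 and edgeR was used, with no version stated. The aligner, the counting tool and the strand setting are not given in the sources used here. Reads from genes that overlap on opposite strands therefore cannot be assigned with certainty, and near-identical gene families (alpha-defensins, Lyz1 and Lyz2, Acot1 and Acot2, Cyp2c, Cyp3a, Ifit1bl1, Sprr2a1 and the Reg3 genes) are uncertain because the counting could have split their reads.

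The deposited counts were whole numbers. The table had 24594 rows, 18127 of them with at least 1 count, and 15 rows without a symbol were kept under their identifier. Total counts per library ranged from 18395427 to 26767043. Genome positions are 1-based and come from the RefSeq annotation of assembly GRCm38.p6, the same assembly as mm10, in which 24570 of the Entrez identifiers were found (99.9%).

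Counts were normalised with TMM factors and filtered with filterByExpr, which left 12592 genes. The test was the edgeR (version 4.0.16, R 4.3.3) quasi-likelihood F-test with robust estimation, two-sided, with group as the only term and 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All per-gene adjusted p-values in the text are from this test unless another is named. Log2 fold changes are NIBR-LTSi over DMSO and carry a standard error (SE). This SE is approximate: it was calculated back from the test, as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD over 3 libraries. The common dispersion of 0.00363 corresponds to a coefficient of variation between replicates of 6.02%. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts were compared within each group for duplicate libraries: the chi-square per degree of freedom was 4.65 to 11.9 over the 6 pairs, so none agreed within sampling noise.

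The procedure was tested on simulated counts with the means and library sizes of this comparison, in which 200 of the 12592 genes were changed. It recovered 83.6% of the genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold. Of its 189 calls, 10 were false (5.29%). The simulated spread followed the dispersion trend alone, and the real comparison called far more genes (42%). These rates therefore need not hold for the real data.

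The tests, the alternatives, 27 gene lists (10 main and 17 secondary) and the rule for named genes were fixed before the data were examined, except where stated. Each list was counted gene by gene and tested as a set with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided), which compares its members with all other tested genes, with Benjamini-Hochberg adjustment over the 26 lists that had a tested member. The mitochondrially encoded list had no row under its symbols and was not analysed here. Named genes were a fixed set of 13 Hippo, stem, regeneration and proliferation genes; the 8 strongest rises and the 8 strongest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups' libraries and a symbol that is not a numbered gene model; and up to 4 tested members per list with the smallest p. This gave 121 tested genes, and Ankrd1, with 36 counts over all libraries, was below the filter. Some of the genes so chosen are not reported here. Other genes named below were chosen after their values were seen, and this is said where they appear, apart from Krr1, named only for its overlap with another gene.

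The alternatives were limma-voom, DESeq2 (version 1.42.0), DESeq2 size factors, upper-quartile factors, library totals only, no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, and each library left out in turn. For lists they were also camera with an estimated correlation, fry, and lists without shared members. An adjustment for gene width was added after the data were seen. Its camera tests ran on width-adjusted log2 CPM, whereas the other camera tests ran on the counts. Camera on log2 CPM without the adjustment was not run, so effects of width and of this change cannot be told apart. Nothing in the table was left unused.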

Results

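Organoids treated with NIBR-LTSi and organoids given DMSO were compared to ask how 24 h of LATS kinase inhibition changes gene expression in the intestinal epithelium. The data are 3 libraries per group, with total counts of 25238809, 18395427 and 21503743 in DMSO replicates 1 to 3 and 19323994, 23945077 and 26767043 in NIBR-LTSi replicates 1 to 3.

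With NIBR-LTSi, 11 of 27 Hippo pathway genes rose, none fell and 16 were not called, with a list median of 1.17-fold. Of 14 YAP and TAZ targets 9 rose and 1 fell. Wwc2 (15.7-fold), Amotl2 (7.15-fold) and Ccn2 (5.45-fold) were among those that rose. Markers of fetal and regenerating intestinal epithelium rose in 16 of 17 cases, and 27 of 28 cell-cycle genes rose by a median of 1.60-fold over the list. Of 16 crypt stem cell markers 6 rose, among them Cdk6, and 3 fell, among them Olfm4 and Lgr5 (a call lost in DESeq2 and in 3 leave-one-out fits). Of 10 Wnt targets 2 rose, Ccnd1 and Myc, and 1 fell, while Axin2 differed by less than its standard error. Enterocyte genes moved both ways, with 8 higher and 12 lower, and the immediate-early genes Fos, Jun and Egr1 fell.

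In all, 5287 of 12592 tested genes changed (42.0%; edgeR quasi-likelihood test, adjusted p under 0.05), 2866 of them higher and 2421 lower with NIBR-LTSi. Most changes were small: 528 genes changed at least 2-fold, 359 higher and 169 lower. In a principal component analysis of log2 CPM, the first component held 51.3% of the variance and separated the groups, and the second (31.2%) spread the libraries within both groups, with NIBR-LTSi replicate 1 at its upper end.

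**Figure D1:**
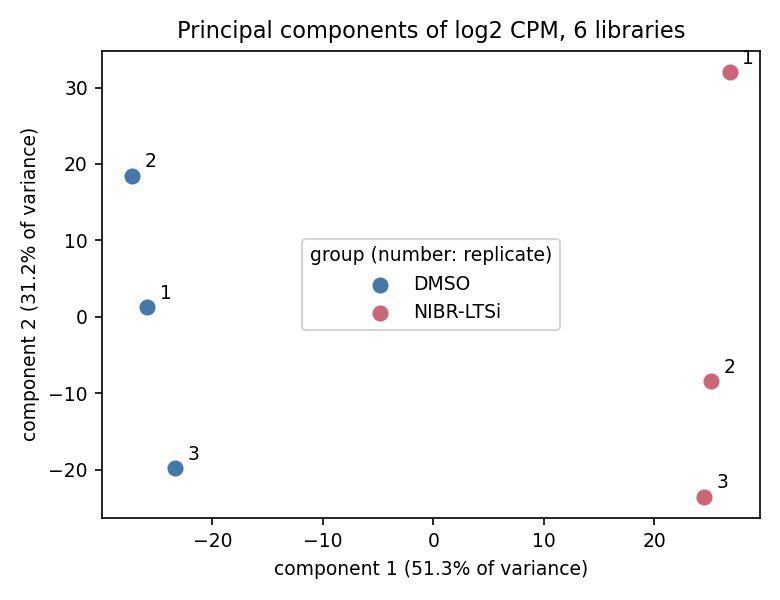
Scores of the 6 libraries on the first 2 principal components of log2 CPM, with DMSO in blue, NIBR-LTSi in red and the replicate number beside each point. The DMSO libraries lie between -27.3 and -23.4 on component 1 and the NIBR-LTSi libraries between 24.5 and 26.9.

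The Hippo pathway list had 11 of 27 tested members higher and none lower (1 was lower without NIBR-LTSi replicate 1 and with DESeq2 size factors, and 2 after the width adjustment). Its median log2 fold change was 0.23, and 16 members were not called. Among these were Stk3, Stk4, Sav1, Mob1a, Mob1b and Nf2, named after their values were seen. Over all tested genes 42% were called. Lats2 and Amotl2 are also in the list of YAP and TAZ targets. Wwc2 (Entrez 52357; chromosome 8, 47826082 to 47990544), a KIBRA-family scaffold that activates LATS kinases, rose from 2.27 ± 0.44 to 35.1 ± 1.7 CPM, a log2 fold change of 3.97 ± 0.11 (SE; adjusted p = 4.90e-10). Its relative Wwc1 (chromosome 11, 35838399 to 35980527) rose from 147 ± 9 to 429 ± 10 CPM. The LIM protein Ajuba (chromosome 14, 54567469 to 54577661), which restrains LATS activity, rose from 3.57 ± 0.18 to 35.7 ± 0.8 CPM (log2 fold change 3.32 ± 0.08, adjusted p = 1.77e-10). The angiomotin-family gene Amotl2 (chromosome 9, 102717091 to 102733418), a YAP target whose product holds YAP in the cytoplasm, rose by 2.84 ± 0.08 on the log2 scale. Of the drug's targets, Lats2 (chromosome 14, 57689662 to 57746212) rose from 8.24 ± 1.15 to 17.3 ± 0.5 CPM, and Lats1 was at 93.9 ± 6.4 and 105 ± 9 CPM (log2 fold change 0.15 ± 0.07, adjusted p = 0.0945; 0.0253 without DMSO replicate 3 and 0.0302 with library totals only). Wwtr1, which encodes TAZ, rose 4.08-fold from a low level of 0.583 ± 0.271 CPM, while Yap1 was at 89.0 ± 1.8 and 82.7 ± 2.4 CPM (log2 fold change -0.11 ± 0.04, adjusted p = 0.0694; 0.0442 without NIBR-LTSi replicate 1, 0.0479 with DESeq2 size factors and 0.00558 after the width adjustment). As a set, the Hippo list was higher than other genes in camera (adjusted p = 6.59e-12), a call that was lost with an estimated correlation (adjusted p = 0.157).

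Of 14 tested YAP and TAZ targets, 9 rose and 1 fell, with a median log2 fold change of 0.94; adjusted over the list alone, 10 rose and 1 fell, and after the width adjustment 2 fell. Ccn2 (chromosome 10, 24595442 to 24598683) rose from 0.680 ± 0.124 to 3.74 ± 0.35 CPM (log2 fold change 2.45 ± 0.22, adjusted p = 3.45e-06). Ccn1 (chromosome 3, 145646971 to 145649985), like Ccn2 a secreted matricellular protein and a standard readout of YAP activity, rose from 18.9 ± 1.0 to 53.8 ± 4.3 CPM (log2 fold change 1.51 ± 0.07, adjusted p = 2.04e-08). F3, which encodes tissue factor, rose 1.99-fold. The member that fell was Gadd45a, a stress-induced growth arrest gene (log2 fold change -0.38), named after its value was seen. The list was higher than other genes in camera (adjusted p = 6.69e-09), with an adjusted p of 0.139 with an estimated correlation.

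**Figure D2:**
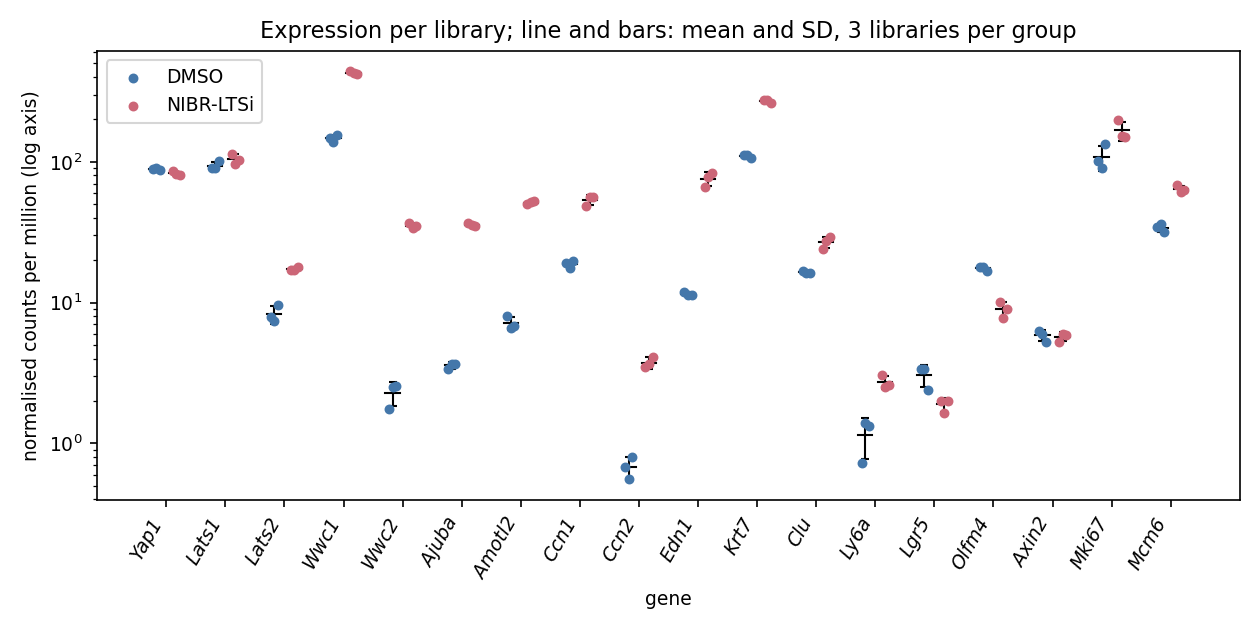
CPM of 18 genes on a log axis, with 1 point per library (DMSO blue, NIBR-LTSi red) and black lines and bars for the mean and SD of 3 libraries. Wwc2, Ajuba and Amotl2 separate most, while Yap1, Lats1, Axin2 and Mki67 did not pass the test.

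Markers of fetal and regenerating epithelium rose in 16 of 17 tested members and none fell, with a median of 2.39-fold. Edn1 (chromosome 13, 42301476 to 42307990), which encodes the peptide endothelin-1, rose from 11.5 ± 0.4 to 75.6 ± 8.7 CPM (log2 fold change 2.72 ± 0.09, adjusted p = 3.99e-09). The annexin Anxa3 rose 3.27-fold and the simple-epithelial keratin Krt7 2.47-fold. Ly6a, which encodes the regeneration marker Sca-1, rose from 1.14 ± 0.37 to 2.71 ± 0.29 CPM (log2 fold change 1.26 ± 0.26, adjusted p = 0.00210), and Clu, the marker of revival stem cells, rose from 16.4 ± 0.3 to 26.8 ± 2.5 CPM (log2 fold change 0.72 ± 0.08, adjusted p = 1.70e-05). This list was higher than other genes in camera (adjusted p = 7.63e-23) and was the only 1 of the 26 lists whose call held with an estimated correlation (adjusted p = 0.0158).

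Of 28 proliferation genes, 27 rose and none fell, and all 28 rose when adjusted over the list alone. The replication helicase subunits Mcm6 and Mcm5 rose 1.87-fold and 1.84-fold, the mitotic activator Cdc20 1.75-fold and the cyclin Ccna2 1.67-fold. Mki67, the gene of the Ki-67 antigen, was at 108 ± 22 CPM with DMSO and 167 ± 26 CPM with NIBR-LTSi (log2 fold change 0.63 ± 0.20, adjusted p = 0.0694); the call was made without DMSO replicate 3 (adjusted p = 0.0241) and by DESeq2 (adjusted p = 0.0194). The camera test of the list gave an adjusted p of 4.00e-20, and an adjusted p of 0.126 with an estimated correlation.

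Crypt base stem cell markers split, with 6 of 16 higher and 3 lower (6 lower after the width adjustment). Olfm4 (chromosome 14, 80000302 to 80023141), an abundant marker of crypt base columnar cells, fell from 17.5 ± 0.7 to 8.96 ± 1.17 CPM (log2 fold change -0.97 ± 0.10, adjusted p = 8.63e-06). Lgr5 (chromosome 10, 115450314 to 115587780), the R-spondin receptor that marks these cells, fell from 3.05 ± 0.56 to 1.89 ± 0.22 CPM (log2 fold change -0.69 ± 0.20, adjusted p = 0.0170). The Lgr5 call was lost without DMSO replicate 1 (adjusted p = 0.0831), without DMSO replicate 2 (0.0636), without NIBR-LTSi replicate 2 (0.0662) and in DESeq2 (0.0521). Against these, the cell-cycle kinase gene Cdk6 rose 3.52-fold, the cotransporter Slc12a2 1.38-fold and the ERBB regulator Lrig1 1.20-fold. The list's median log2 fold change was -0.04 (0.08 without DMSO replicate 1 and 0.01 with library totals only), while its mean (0.06) and its camera direction were upward (adjusted p = 0.335).

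Among 10 tested Wnt targets, 2 rose and 1 fell (2 fell in limma-voom and with the filter of at least 1 CPM, and none in DESeq2 or without DMSO replicate 1, DMSO replicate 2 or NIBR-LTSi replicate 2). Ccnd1, which encodes cyclin D1, rose 2.49-fold and Myc 1.38-fold, and the member that fell was Lgr5. Axin2 was at 5.84 ± 0.54 and 5.73 ± 0.41 CPM (log2 fold change -0.02 ± 0.12, adjusted p = 0.892), with a sign that turned when only library totals were used and without DMSO replicate 1 or NIBR-LTSi replicate 1. Sp5 had a log2 fold change of -0.84 ± 0.34 (adjusted p = 0.0661; 0.0494 in limma-voom and 0.0476 with the filter of at least 1 CPM). In the Notch list, 3 of 9 members rose and 2 fell (5 and 2 without DMSO replicate 3): the ligand genes Jag2 (2.65-fold), Jag1 (1.55-fold) and Dll1 (1.22-fold) rose, while Dll4 fell 1.86-fold. Nrarp was the other member that fell (log2 fold change -0.44, adjusted p = 4.26e-04), and Hes1, Notch1, Notch2 and Atoh1 were not called. These last 5 genes were named after their values were seen. Camera gave adjusted p-values of 0.168 for the Wnt and 0.262 for the Notch list.

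The enterocyte list had 8 of 25 members higher, 12 lower and 5 not called. Lct, which encodes the brush-border lactase, rose from 54.1 ± 4.7 to 200 ± 11 CPM (log2 fold change 1.89 ± 0.06, adjusted p = 4.40e-09), and the aminopeptidase gene Enpep rose from 605 ± 16 to 1166 ± 31 CPM. In the other direction, the trehalase gene Treh fell from 449 ± 9 to 215 ± 5 CPM (log2 fold change -1.06 ± 0.04, adjusted p = 1.47e-09), and Fabp2, the intestinal fatty acid binding protein, fell from 2182 ± 106 to 1114 ± 48 CPM. As a set the list was lower than other genes in camera (adjusted p = 0.0271), with a median log2 fold change of -0.08. The call was lost without NIBR-LTSi replicate 2 (adjusted p = 0.0592), without NIBR-LTSi replicate 3 (0.0764) and with an estimated correlation (0.446). It was also lost after the width adjustment, where camera ran on log2 CPM (adjusted p = 0.228). The list median was then -0.10, so this loss cannot be credited to gene width alone.

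Secretory lineage markers also moved both ways. In the goblet list, 4 of 17 members rose and 3 fell (2 rose without DMSO replicate 1 and in DESeq2, and 5 fell without DMSO replicate 3). Clca1 (chromosome 3, 145004537 to 145032776), a secreted mucus protein, rose from 234 ± 4 to 792 ± 4 CPM and had the smallest p among the 121 named genes (log2 fold change 1.76 ± 0.03, adjusted p = 3.55e-11). The mucus lectin Zg16 rose 1.33-fold, while Spink4 fell 1.65-fold and the kallikrein Klk1 1.68-fold. In the Paneth list, 3 of 14 members rose and 6 fell, or 7 adjusted over the list alone. Lyz1, the Paneth cell lysozyme, fell 1.48-fold, Clps 2.04-fold and the lectin Itln1 1.33-fold, and the matrix metalloproteinase Mmp7 rose 1.60-fold. Of 19 enteroendocrine genes, 3 rose and 6 fell, and only 1 rose in DESeq2 and when DMSO replicate 1, 2 or 3 or NIBR-LTSi replicate 2 or 3 was left out. The granins Chgb and Chga fell 1.42-fold and 1.35-fold, the ghrelin gene Ghrl fell 1.77-fold, and the proglucagon gene Gcg rose 1.54-fold. In the tuft list, 2 of 9 members fell and none rose: Ltc4s (2.30-fold) and the interleukin-25 receptor gene Il17rb (2.14-fold), while Dclk1 (1.06 ± 0.19 and 1.48 ± 0.35 CPM) and Trpm5 were not called. Camera separated none of these 4 lists from other genes, with adjusted p-values of 0.563 (goblet), 0.254 (Paneth), 0.0827 (enteroendocrine; 0.0462 without DMSO replicate 3 and 0.0410 with no low-count filter) and 0.431 (tuft). The goblet median (-0.06; 0.01 after the width adjustment) and mean were downward and its camera direction upward.

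**Figure D3:**
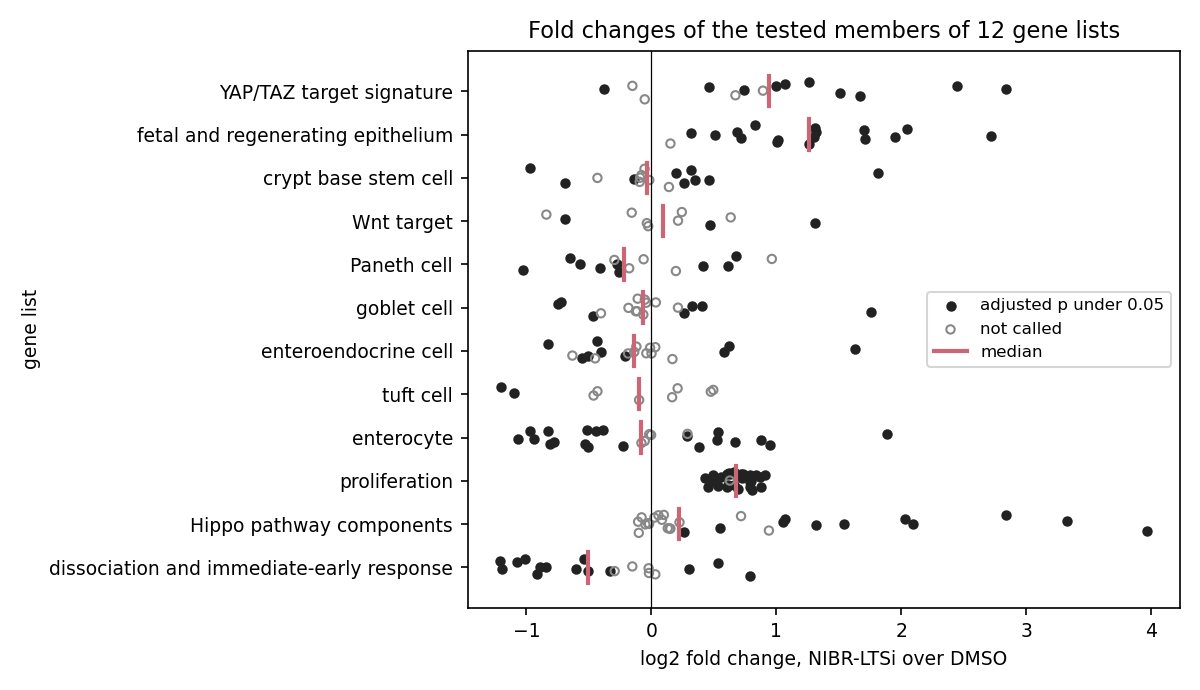
Log2 fold changes of the tested members of 12 gene lists, 1 point per gene, filled where the adjusted p was under 0.05 and open where it was not, with the list median as a red line. The medians lie at 0.94 for YAP and TAZ targets, 1.26 for fetal and regenerating epithelium, 0.68 for proliferation and -0.51 for the immediate-early list.

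The strongest rises under the fixed rule were Wwc2, Glipr1 (15.0-fold), Ajuba, the glycosyltransferase Mgat4c (9.97-fold), the integrin-linked cytoskeletal gene Tln2 (7.44-fold), the synaptotagmin Syt8 (7.41-fold), Amotl2 and Fgfr4 (7.14-fold), a receptor for the enterokine FGF15. Glipr1 (chromosome 10, 111985448 to 112002639), which overlaps Krr1, rose from 2.59 ± 0.46 to 38.5 ± 1.2 CPM (log2 fold change 3.90 ± 0.10, adjusted p = 2.90e-10). The strongest falls were Ttr (5.15-fold), the chymotrypsinogen gene Ctrb1 (4.18-fold), the iodotyrosine deiodinase Iyd (4.01-fold), the transcription factor Klf2 (3.38-fold), Sectm1b (3.07-fold), Bbox1, which makes carnitine (3.07-fold), the amino acid transporter Slc7a15 (2.98-fold) and Cst6, a cystatin (2.85-fold). Ttr (chromosome 18, 20664209 to 20674326), the carrier of thyroxine and retinol-binding protein, fell from 10.7 ± 0.5 to 2.06 ± 0.42 CPM (log2 fold change -2.36 ± 0.14, adjusted p = 1.59e-07). In each of these 16 genes every NIBR-LTSi library lay beyond every DMSO library, as the rule required.

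Of 27 genes of extracellular matrix, adhesion and actin, 13 rose and 2 fell (14 and 2 adjusted over the list alone; 1 fell in DESeq2 and without DMSO replicate 1, DMSO replicate 3 or NIBR-LTSi replicate 1, and 4 after the width adjustment). The laminin chain gene Lamb3 rose 1.99-fold, the actin crosslinker Flna 3.56-fold and the tropomyosin Tpm4 1.30-fold (camera adjusted p = 5.39e-05; adjusted p = 0.128 with an estimated correlation). In the EGF and ERK list, 10 of 18 members rose and 1 fell, or 13 and 2 adjusted over the list alone (2 fell without DMSO replicate 2 and after the width adjustment). The ERK feedback inhibitors Spry1 and Spred1 rose 2.46-fold and 1.62-fold and Phlda1 2.19-fold, while the ERK phosphatase Dusp5 fell 1.82-fold from 188 ± 3 CPM (camera adjusted p = 0.0655, and 0.0462 without DMSO replicate 3, 0.0406 without NIBR-LTSi replicate 1, 0.0420 without NIBR-LTSi replicate 3, 0.0446 with the replicate block, 0.0240 with no low-count filter and 0.0127 after the width adjustment). In the BMP list, 4 of 9 members rose and none fell: Bmp2 (2.22-fold) and the BMP-induced genes Id4 (2.83-fold), Id2 (1.93-fold) and Id3 (1.28-fold). Id1, Smad6, Smad7, Bambi and Bmp7, named after their values were seen, were not called. The Id3 call was lost when any 1 of the 6 libraries was left out except DMSO replicate 2, in DESeq2, with the replicate block (adjusted p = 0.0745) and with no low-count filter (0.0652). The list's camera adjusted p was 0.0828 (0.0448 without DMSO replicate 2, 0.0471 without NIBR-LTSi replicate 1, 0.0495 with no low-count filter and 0.0439 with the filter of at least 1 CPM).

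In the list of NF-kB and inflammatory mediators, 4 of 10 members rose and 3 fell (5 and 3 adjusted over the list alone). The cytokine gene Il18 rose from 57.7 ± 1.9 to 167 ± 6 CPM (log2 fold change 1.53 ± 0.05, adjusted p = 9.09e-10). The chemokine Cxcl16 rose 2.47-fold and Nos2 3.84-fold, and the NF-kB subunit gene Relb fell 1.40-fold. The list's camera adjusted p was 0.0109, and 0.259 with an estimated correlation. After the width adjustment, where camera ran on log2 CPM, it was 0.310. In the interferon list, 7 of 18 members fell and 3 rose. Irf7, the regulator of type I interferon genes, fell 2.07-fold, the antiviral Oas1a 2.50-fold and Oasl1 1.52-fold. Ifit1bl1, which overlaps other Ifit genes, rose 2.12-fold. Also higher were Ifit2 (log2 fold change 2.80, adjusted p = 1.23e-04) and Ifi27l2b (0.16), both named after their values were seen. The list's camera adjusted p was 0.0804.

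Among 22 genes of cholesterol synthesis, 13 rose and 3 fell (14 and 3 adjusted over the list alone). Acat2 rose 1.60-fold, the sterol carrier Stard4 1.43-fold and Idi1 1.34-fold, while Insig1, which retains SREBP in the endoplasmic reticulum, fell 1.30-fold. The camera call of this list (adjusted p = 0.0335) was lost without DMSO replicate 1 (0.0587), with DESeq2 size factors (0.0571) and with an estimated correlation (adjusted p = 0.446). Of 22 xenobiotic response genes, 12 fell and 2 rose. The cytochromes Cyp2c29 and Cyp3a25 fell 1.84-fold and 1.56-fold and the carboxylesterase Ces2a 1.46-fold, and Gclc, the rate-limiting enzyme of glutathione synthesis, rose 1.51-fold (camera adjusted p = 0.00434; adjusted p = 0.446 with an estimated correlation). In the unfolded protein and integrated stress list, 8 of 18 members rose and 5 fell. The serine synthesis enzymes Psat1 and Phgdh rose 2.18-fold and 1.81-fold and the asparagine synthetase Asns 1.86-fold, whereas Herpud1, a gene of endoplasmic-reticulum-associated degradation, fell 1.38-fold (camera adjusted p = 0.262). The p53 list had 3 of 16 members higher and 3 lower: Ckap2 rose 1.64-fold and Ccng1 1.12-fold, and Trp53inp1 and Fas fell 1.37-fold and 1.33-fold. Its median log2 fold change was 0.08 and its camera direction downward (adjusted p = 0.920).

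Few markers of other epithelia were abundant enough to test. Of 6 tested genes of stratified epithelium, 4 rose and none fell (1 fell without DMSO replicate 3). The keratin Krt23 rose 2.53-fold and the cornified envelope gene Sprr2a1 2.13-fold from 51.7 ± 0.9 CPM, and Krt4 rose from 0.263 ± 0.166 to 2.31 ± 0.38 CPM. Krt14, a keratin of basal cells, had 3 counts over the DMSO libraries and 137 over the NIBR-LTSi libraries, a ratio of 41.2 after scaling (exact 95% binomial interval 13.8 to 202, counting error only). Krt5, its usual partner in basal cells, named after its counts were seen, was below the filter, with 749 of its 754 counts in NIBR-LTSi replicate 2. The list's camera adjusted p was 1.48e-04, and the adjusted p was 0.129 with an estimated correlation. In the stomach list, 3 of 5 members rose and none fell: Muc1 (2.67-fold, from 0.644 ± 0.106 CPM), Tff1 (1.58-fold) and Anxa10 (1.16-fold), with Vsig1 not called (camera adjusted p = 0.335); the Anxa10 call was lost in DESeq2 and without DMSO replicate 3, NIBR-LTSi replicate 2 or NIBR-LTSi replicate 3. Only 2 of 18 mesenchymal genes were abundant enough to test, Vim (6.69 ± 1.23 and 5.08 ± 0.33 CPM, adjusted p = 0.0431) and Pdgfrb (adjusted p = 0.0771); both were lower when adjusted over the list alone, and the Vim call was lost without DMSO replicate 2 (log2 fold change -0.24 against -0.39) and in 3 other leave-one-out fits, those without NIBR-LTSi replicate 1, 2 or 3. It was also lost in limma-voom (adjusted p = 0.0535), in DESeq2 (0.113) and with library totals only (0.0703). Of 18 immune and endothelial genes, 5 were tested: Lyz2 was lower (0.752 ± 0.215 and 0.375 ± 0.086 CPM, adjusted p = 0.0427), a call lost without any 1 of the 6 libraries, in DESeq2 (0.208), with library totals only (0.0506), no low-count filter (0.103) or the replicate block (0.0741), and when adjusted over the list alone. Itgam (0.0333 with library totals only), Pecam1 (0.0412 without NIBR-LTSi replicate 2) and Csf1r were not called. Camera gave adjusted p-values of 0.464 and 0.812 for these lists.

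Immediate-early genes respond within minutes to growth factors and to tissue dissociation. Of 19 members of the dissociation and immediate-early list, 11 were lower and 3 higher. Egr1 fell from 553 ± 24 to 242 ± 17 CPM (log2 fold change -1.19 ± 0.05, adjusted p = 2.58e-08), Fos from 705 ± 18 to 393 ± 14 CPM, Jun from 336 ± 10 to 179 ± 9 CPM and the antiproliferative gene Btg2 from 205 ± 4 to 97.0 ± 4.2 CPM. All organoids were dissociated before RNA extraction, which bears on this list. The list was lower than other genes in camera (adjusted p = 1.47e-09; adjusted p = 0.157 with an estimated correlation).

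In lists for which no separate value is given, the counts adjusted over the list alone equalled those over all tested genes. Calls with small fold changes rest on a spread between replicates of about 6.02%, which technical replicates could also show, and the fold changes carried a trend with gene width, from a median log2 value of -0.07 in the narrowest of 10 width classes to 0.11 in the widest.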

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

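The width adjustment and the tests that use it were chosen after the data were seen; the other alternatives were fixed before the data were examined. The counts of changed, higher, lower and at least 2-fold changed genes stayed within 1.5 times the reported counts in all 15 alternatives that give them, with 4212 to 5645 changed genes and 413 to 590 at least 2-fold. The share of calls that were higher was 54.2%, with a range of 49.2% (width-adjusted) to 64.1% (library totals only). DESeq2 gave 4363 calls, with no adjusted p for 4220 genes. Residual correlations of same-numbered libraries were -0.368, -0.0484 and 0.137, and those of unlike-numbered pairs lay between -0.316 and 0.295. So few pairs with so wide a spread cannot show whether same-numbered libraries shared a culture. With the numbers as a replicate block there were 4945 calls. Among the main lists, the YAP and TAZ (adjusted p = 0.139), enterocyte (0.446) and proliferation (0.126) lists lost the camera threshold with an estimated correlation. The enterocyte list also lost it after the width adjustment (0.228), where camera ran on log2 CPM and not on the counts. With no low-count filter the enteroendocrine list passed (0.0410). Fry asks only whether a list's genes move on balance one way. In fry the crypt stem (adjusted p = 0.00127), Wnt (0.00214) and goblet (0.00498) lists passed upward and the enteroendocrine list (0.00648) downward. The Notch (0.00155), EGF and ERK (9.48e-04), BMP (0.00553), unfolded protein (0.00289) and stomach (0.00335) lists also passed upward. The interferon (5.16e-04) and mesenchymal (0.00389) lists passed downward. With 1 library left out, the adjusted p ranged from 0.0114 to 0.0764 for enterocytes and from 0.0462 to 0.122 for the enteroendocrine list. Directions reversed for goblet genes after the width adjustment (0.892), for immune and endothelial genes with the stricter filter (0.790), and for the p53 list with no filter (0.988), after the width adjustment (0.856), in fry (0.290) and with a library left out (range 0.838 to 0.972), none of them near the threshold. Axin2 reversed with library totals only (log2 fold change 0.0204) and with a library left out (range -0.0978 to 0.0340). The causes of these changes were not tested. Depth limits the low genes: Ccn2 had 10 to 17 counts per DMSO library and Ly6a 18 to 28, against 319 to 480 for Ccn1.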

Other observations

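All tests in this part were chosen after the data had been seen. For the PPAR-alpha, villus, heat-shock and width-adjusted list tests, the outcome that would count against the explanation was set before the tested values were seen, and genes already looked at were left out of the first 3.

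Among genes of fatty acid use, Acot1 fell 2.72-fold and Bbox1, which makes carnitine, 3.07-fold, and the fatty acid binding protein Fabp1 fell 1.43-fold (from 7372 to 5151 CPM). The hypothesis that targets of the nuclear receptor PPAR-alpha fell as a group was tested on 19 targets not yet looked at, of which 14 were lower and 1 higher (median log2 fold change -0.41). They included Angptl4 (1.91-fold lower), the lipid droplet gene Plin2 (1.55-fold), the peroxisomal enzyme Ehhadh (1.55-fold) and the mitochondrial enzyme Acadl (1.55-fold). These 19 genes were lower than other genes in camera (p = 1.08e-08; p = 0.0837 with an estimated correlation). The predicted fall of the group thus held only with the preset correlation. It does not show that PPAR-alpha caused the fall, because the activity of the receptor was not measured. Of all 22 targets 16 fell and 2 rose: Vnn1 5.95-fold and Pdk4 1.96-fold from 0.989 CPM.

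Enterocytes also express many of these genes, but a smaller share of enterocytes would lower their markers alike. Of 25 enterocyte genes 8 rose, which argues against a smaller share as the whole cause of the changes in that list. The bar for this was set after the counts were seen. Whether a smaller share contributed to the falls, including those of the genes of fatty acid use, was not tested. The opposite directions raised the hypothesis of a shift along the villus, from mid-villus toward villus bottom programmes. Of 11 mid-villus nutrient transporters 9 fell, among them Slc6a19 (1.84-fold) and Slc2a5 (1.77-fold), and 1 rose, Slc7a6 (1.61-fold), while the bottom genes Reg3b (2.69-fold) and Il18 (2.89-fold) rose. In genes not yet looked at, however, the bottom list (4 of 6 lower, among them Lypd8 and Reg1, and 1 higher; median log2 fold change -0.23) lay no higher than the mid-villus list (4 of 6 lower and 1 higher; -0.20), with a difference of medians of -0.0298, where the hypothesis needed the bottom list to lie above. Villus tip genes went both ways, with 2 of 6 higher and 2 lower (median 0.07); the nucleoside transporter Slc28a2 rose 7.70-fold from 0.910 CPM and the lipid regulator Creb3l3 fell by 0.59 on the log2 scale.

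The fall of the immediate-early genes Fos, Jun, Egr1 and Btg2 could come from less dissociation stress in the treated libraries, since all organoids were dissociated before extraction. Such stress also induces heat-shock chaperones, so these would fall too unless something else raised them. The 8 chaperones not yet looked at had a median log2 fold change of 0.256, with 6 higher, such as Hspd1 (1.36-fold) and Hsp90aa1 (1.34-fold), and 1 lower, Bag3 (1.13-fold). Of the chaperones already looked at, Hsph1 and Hspa1b were higher, and Hspa1a, Hspa8 and Dnajb1 were not called. The chaperones thus did not fall as a group. A rise from another effect of the treatment could hide a fall, so the test cannot decide about weaker stress. A handling difference that touches immediate-early genes alone, and an effect of the inhibitor itself, stay open and were not tested.

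The median log2 fold change rose with gene width, from -0.07 in the narrowest of 10 width classes to 0.11 in the widest (9315 bases or more). One candidate explanation is that libraries recover long transcripts unequally. The slope of log ratio on log2 width was higher in the treated library in 9 of 9 pairs of a treated and a DMSO library (-0.0757 to 0.0147 for DMSO, 0.0194 to 0.0450 for NIBR-LTSi), but the gap between the groups, 0.00477, was below the SD of slopes within groups, 0.0333, a bound made stricter after the slopes had been seen. Unequal recovery and a response that differs with gene width cannot be told apart for this trend, because each library was prepared once. With the trend taken out and camera run on log2 CPM, 3 of 3 tested lists kept an adjusted camera p under 0.05. The values were 7.19e-04 for YAP and TAZ targets, 2.34e-09 for fetal and regenerating epithelium and 3.34e-14 for proliferation. The list medians on the log2 scale were 0.94, 1.26 and 0.68, far above the span of the trend, so this outcome was nearly given and adds little. The sizes alone argue against the trend as the whole origin of those changes. Without this adjustment, however, an estimated correlation in camera ended the YAP and TAZ (adjusted p = 0.139) and proliferation (0.126) calls.

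Keratin genes of skin and hair appeared in single libraries. Krt5 had 749 counts in NIBR-LTSi replicate 2 and 3 or fewer in each of the others, Krt2 had 119 counts in DMSO replicate 1 and 1 over the rest, Krt73 had 324 and 60 counts in NIBR-LTSi replicates 2 and 1 and 1 over the rest, and Krt83 had 182 counts in NIBR-LTSi replicate 3 and 10 to 33 elsewhere. These 4 genes lie on chromosome 15 between 101485130 and 101818956, in the cluster that also holds the abundant Krt7 and Krt8. Reads shared with Krt8 would keep 1 ratio in all libraries, but Krt5 counts per Krt8 count were 187 times as high in NIBR-LTSi replicate 2 as in the next library. Basal cells in that library would bring Krt14, whose count per library total, without TMM, was 1.01 times the mean of the other treated libraries, and Trp63, which had 1 count. An amplification or alignment event particular to a library stays open, needs the reads, and could also bear on Krt14 and Krt4, although both of those rose in all 3 treated libraries.

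Some transcripts varied between libraries of the same group. The ribosomal precursor Rn45s took 0.522% of counts in NIBR-LTSi replicate 3 and 0.159% to 0.291% in the others, and Lars2 (356 CPM in that library, 97.2 to 218 CPM elsewhere) and Mir6236 were highest in the same library. Neat1 was at 313 to 565 CPM in the DMSO libraries and at 90.2, 251 and 247 CPM in NIBR-LTSi replicates 1 to 3 (log2 fold change -1.12 ± 0.50, adjusted p = 0.158).

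Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real grouping, the real one itself (5287), and the highest of the other 9 gave 0 in edgeR (28 to 314 genes at an unadjusted p under 0.05, against 6244). With 10 splits no share under 0.05 is possible. Each of the other 9 splits puts treated and DMSO libraries together in both groups, so the difference between treatments widens their spread within groups. Few calls in those splits were therefore to be had in any case. Their counts are no baseline for the real grouping, and the splits cannot decide about it.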
